A study of Mus musculus with 16 samples.

How the data were processed

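Total RNA of mouse embryonic fibroblasts was labelled with biotin and hybridised to Affymetrix arrays that hold 45101 probe sets, 16 arrays in all. Per the labels, the fibroblasts came from the whole body of 13.5-day embryos and were grown in DMEM with 15% fetal bovine serum at 37 °C and 7% CO2, and the labelled cRNA was made from 2 ug of Trizol-extracted RNA. The values used are the log2 expression values deposited by the authors, made with RMA per the submitters' processing notes; the version of RMA and the probe set definition are not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set on a log2 scale. It compresses small signals, so the change of a gene near the lowest levels is understated. The values of all arrays ran from 3.09 to 15.21, and the array medians lay between 6.96 and 7.02.

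The 4 groups were taken from the sample labels, 4 arrays in each. The labels number the arrays of a group as biological replicates and do not say which embryos they came from or on which day they were processed. Hence p-values measure the spread between these arrays, and a difference in culture or scan day between groups could not be tested. The number of arrays limits the precision. Deviations from the group means did not pair arrays of the same number, so no block for the replicate number was used.

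After 64 control probe sets were left out, 34945 probe sets were named with 1 gene by the platform annotation, 932 with several genes and 9160 with none. Of those with 1 gene, 34741 had a gene identifier in the mouse gene table of assembly GRCm38.p6, which changed 0 symbols. No probe set was named Pten in the annotation used here, so the level of Pten was not analysed here and the genotype labels could not be checked by it. Other settings for its log2 change were not run for the same reason. The 18193 genes were each represented by the probe set with the highest mean over all 16 arrays, which mattered for 9010 genes with more than 1 probe set. Genes below the 30th percentile of mean level (log2 6.57) were not tested, which left 12735. No column of per-array values was left unused.

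Each comparison was a contrast of group means in 1 linear model over all 16 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 12 residual degrees of freedom, two-sided moderated test). Adjusted p-values are Benjamini-Hochberg values over the 12735 genes, and 0.05 was the threshold. The contrasts were F341V against wild type, Pten deletion with Cre against wild type with Cre, the difference between these 2 effects, and wild type with Cre against wild type without Cre. The model, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named, for each mutant contrast, up to 10 genes with the greatest rise and 10 with the greatest fall among genes past the threshold whose mutant arrays all lay on one side of all control arrays. It also named up to 4 members with the smallest p of each list described, genes called in both mutants, the 10 genes with the smallest p for the difference of the effects, and the 5 greatest rises and falls between the wild type groups. Genes named outside this rule are said to be so.

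A set of 38 gene lists held 771 members, of which 717 had a probe set, and 36 lists with at least 5 tested genes were tested. List tests used camera with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance one way without comparing them with other genes, stood beside it. Members were counted as past the threshold over all genes tested and adjusted over the list alone. Lists share members, so their tests are not independent. Overlaps and neighbours of Pten were tested with Fisher's exact test, two-sided. The order of genes along the chromosome came from GRCm38.p6 and was used only to find neighbours. The correlation of the 2 mutant effects across genes was set against 99 draws with the arrays relabelled within each strain and vector, where 100 had been set, because the real labels were counted as 1.

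The model was tested on simulated data with the means and spreads of these arrays. The noise was drawn independently for each gene and array. The simulation thus left out structure shared between genes, and its false calls do not measure error under such structure. In the F341V contrast it recovered 63% of 100 genes changed by 0.5 and 91% of 100 genes changed by 1 on the log2 scale among 12735 genes, with 4 false calls and 0 of the wrong sign. With no gene changed in the deletion contrast it called 0 genes. Alternatives covered the arrays in the fit, the eBayes prior, array weights, normalization, the filter, the treatment of several probe sets, the replicate number, the sex of the embryos, stricter thresholds and leaving out each array in turn. The alternative for the eBayes prior was not run for the lists. After the data were seen, 4 more settings were added: without wild type 3, wild type 4 and F341V 4, with these arrays as a covariate, with only these arrays of their 2 groups, and with only the Y-positive array of the deletion group. A covariate made from the main component of the deviations within groups was also fitted and dropped, because by construction it cannot differ between groups and so makes the spread too small. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.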

Results

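Gene expression was compared between fibroblasts with an altered Pten gene and fibroblasts with the wild type gene. Pten encodes a lipid phosphatase that opposes signalling through PI3K and AKT. Wild type fibroblasts and fibroblasts homozygous for the Pten F341V alteration were of the FVB/N strain and had no Cre. The other groups had received the pBP-Cre vector and came from a stock that the labels describe as FVB/N derived from a 129Sv/Ev and Black Swiss mix. They carried either wild type Pten or floxed Pten, which Cre deletes. Each of the 4 groups had 4 arrays. Correlations between arrays of a group ran from 0.9719 to 0.9962 in wild type, from 0.9702 to 0.9973 in F341V, from 0.9812 to 0.9959 in wild type with Cre and from 0.9897 to 0.9936 in the deletion.

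On the first component (51.9% of the variance) 3 arrays without Cre lay nearer to the arrays with Cre than to the other 5. Wild type 3, wild type 4 and F341V 4 lay at -1.12, 1.18 and 3.80, and the other 5 arrays without Cre between -32.89 and -30.6. The arrays with Cre lay between 9.02 and 27.21, so this component did not follow strain and vector alone. The mean log2 level of 23 mitosis genes was 11.07, 11.14, 10.29 and 10.19 in wild type 1 to 4 and 11.16, 11.10, 11.12 and 10.13 in F341V 1 to 4. The 25 DNA replication genes averaged 11.08, 11.18, 10.39 and 10.36 in wild type and 11.22, 11.17, 11.17 and 10.31 in F341V. Lysosome genes went the other way, at 11.19, 11.25, 11.84 and 11.78 in wild type and 11.26, 11.14, 11.16 and 11.83 in F341V. The arrays also differed by sex. The mean log2 level of 3 Y-linked genes was 8.17 or more in wild type 2, F341V 4, each array of wild type with Cre and deletion 2. It was 4.43 or less elsewhere.

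**Figure D1:**
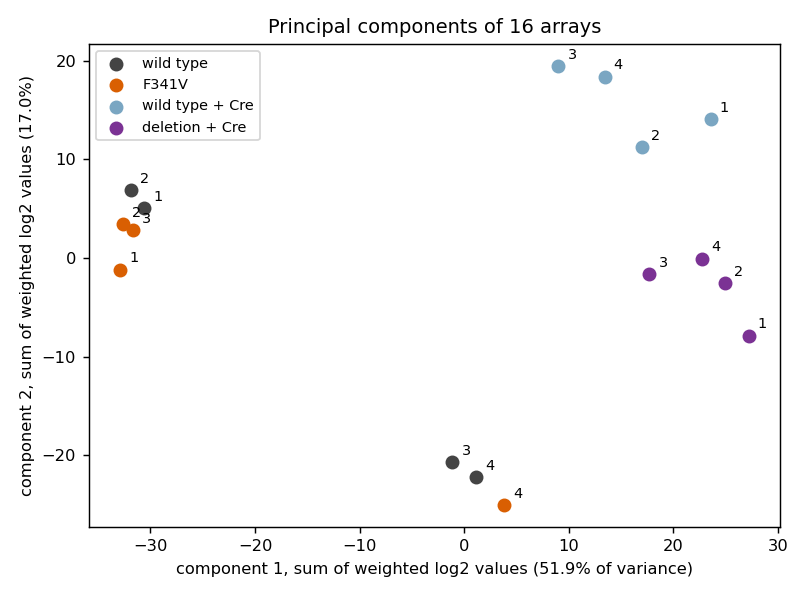
The first 2 principal components of 12735 genes on 16 arrays, with the replicate number beside each point and the share of variance on each axis. Wild type 3, wild type 4 and F341V 4 sit apart from the other 5 arrays without Cre, and the arrays with Cre lie to the right.

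F341V fibroblasts differed from wild type fibroblasts of the same strain in 5 of 12735 genes. Nefl, the light chain of neurofilaments, was 1.95-fold higher, at log2 8.02 ± 0.11 in F341V against 7.06 ± 0.12 in wild type (SD, n = 4; adjusted p = 0.00272). Lipo3, a gene of the acid lipase family next to Pten, was 2.26-fold higher, from a low 6.22 ± 0.18 in wild type (log2 change 1.18, SE 0.14, adjusted p = 0.00272). The matrix glycoprotein gene Thbs1 fell from 13.88 ± 0.09 to 13.40 ± 0.13 (adjusted p = 0.0301), and Tgfa, which encodes a ligand of the EGF receptor, from 7.92 ± 0.09 to 7.34 ± 0.05 (adjusted p = 0.0025). Als2cl, a relative of the exchange factor gene Als2, fell from 7.54 ± 0.08 to 6.77 ± 0.14 (adjusted p = 0.00272). For each of these genes the 4 F341V arrays lay on one side of the 4 wild type arrays. Non-overlapping arrays were seen for 474 genes, or 3.72%, where chance gives 2.86%, and 812 genes had an unadjusted p under 0.05. Without wild type 3, wild type 4 and F341V 4 there were 15 calls, 4 of them among the 5 genes, and with these arrays as a covariate 13, which held the 5 genes. Leaving out F341V 4 alone gave 26 calls, array weights gave 36, and no gene passed when genes under the 50th percentile of level were left out. That filter removed Lipo3, Nefl, Als2cl and Tgfa, so only Thbs1 of the 5 genes was tested again there (adjusted p = 0.105). The Thbs1 call ended in 11 of 21 alternatives (adjusted p 0.0112 to 1 over them), among them without wild type 1 (0.1), 2 (0.0709), 3 (0.0711) or 4 (0.0938) and without F341V 1 (0.18) or 2 (0.157), the Lipo3 call ended with only the groups compared in the fit (adjusted p = 0.154, and 0.000147 to 0.154 over its alternatives), and the Tgfa call ended with the mean of its probe sets (log2 change -0.21, adjusted p = 0.317, against 0.00018 to 1 over its alternatives).

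Among the gene groups, markers of skeletal muscle stood highest in F341V. The 12 tested members had a median log2 change of 1.12 (camera adjusted p = 1.19e-07; adjusted p = 0.279 with an estimated correlation). None passed the test over all genes, and 5 were higher when adjusted over the list alone. Tnnt1, a troponin of slow muscle, had a log2 change of 1.86 (SE 0.53), the myosin light chain genes Mylpf and Myl4 of 1.39 (SE 0.40) and 1.49 (SE 0.47), and Tnnc1 of 1.24 (SE 0.41), with adjusted p-values from 0.543 to 0.632. The list averaged 8.60, 8.69, 8.17 and 7.86 in wild type 1 to 4 and 10.38, 9.59, 9.09 and 8.16 in F341V 1 to 4, so F341V 4 lay below 3 of the wild type arrays. Markers of nerve and glia had a median change of 0.18 (camera adjusted p = 0.000482; adjusted p = 0.0378 with an estimated correlation), with Nefl past the test over all genes and 3 of 11 higher when adjusted over the list alone. Fabp7, a fatty acid binding protein of glia, was at 1.38 (SE 0.24, adjusted p = 0.0733) and the neurofilament gene Nefm at 0.80 (SE 0.15, adjusted p = 0.116). Markers of cartilage and bone lay lower, with a median of -0.17 (camera adjusted p = 0.00155; adjusted p = 0.0747 with an estimated correlation), including Col2a1 at -0.90 and Comp at -1.03. Neither was past the test over all genes.

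Genes of the response to TGF-beta and BMP also lay lower in F341V. Their median change was -0.19 (camera adjusted p = 0.00155; adjusted p = 0.0392 with an estimated correlation), and 14 of 16 members were below 0. Ltbp2, which encodes a protein that binds latent TGF-beta, was at -0.72 (SE 0.20), the inhibitory Smad gene Smad6 at -0.63 (SE 0.20) and Tgfb2 at -0.37 (SE 0.13), with no member past the test over all genes or over the list. The 22 genes of the ATF4 and amino acid response had a median of 0.20 (camera adjusted p = 0.00155; adjusted p = 0.786 with an estimated correlation), 21 of them above 0 and none past the test. These lists, skeletal muscle, nerve and glia, and cartilage and bone were past camera's threshold without any 1 of the 8 arrays, and the other 10 of the 15 lists past it were not. Growth factors and their receptors had a median of -0.13, with Igf1r at -0.34 and Fgf7 at -0.62 lower when adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.227 with an estimated correlation), and markers of blood cells a median of 0.22 (camera adjusted p = 0.0122; adjusted p = 0.712 with an estimated correlation). The growth factor call ended without wild type 2 (0.0653), wild type 4 (0.101) or F341V 1 (0.0681), and the blood cell call without wild type 1 (0.0739), wild type 4 (0.0784), F341V 1 (0.667) or F341V 4 (0.0517).

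The lists that moved with the 3 arrays apart included those of cell division. DNA replication, mitosis and DNA repair had medians of 0.20, 0.18 and 0.19 in F341V (camera adjusted p = 0.00384, 0.0296 and 0.0294), and adjusted p-values of 0.887, 0.887 and 0.847 with an estimated correlation. None of their 25, 23 and 12 members passed the test over all genes. Of the 3 arrays with low mitosis levels, 2 were wild type and 1 was F341V, and without these arrays the medians were 0.06, 0.01 and 0.06 (camera adjusted p = 0.648, 0.977 and 0.335). Leaving out any 1 of wild type 3, wild type 4 and F341V 1 to 3 also ended these calls (0.0582 to 0.412, 0.262 to 0.868 and 0.107 to 0.412). Lysosome genes (median -0.14; 20 members) and p53 target genes (-0.07; 20 members), both higher in the same 3 arrays, had camera adjusted p-values of 0.00154 and 0.00643, and 0.79 and 0.712 with an estimated correlation. Their medians without the 3 arrays were -0.03 and -0.01, and both calls ended without wild type 3 (0.157 and 0.0608) or wild type 4 (0.119 and 0.0904), the p53 call also without F341V 1 (0.0892). HOX genes had a median of -0.16 (camera adjusted p = 0.000792, 0.649 with an estimated correlation), which was -0.05 without the 3 arrays (0.135) and ended as a call without wild type 4 (0.0724). Fat cell markers had a median of -0.19 and glycolysis genes of 0.07 (camera adjusted p = 0.0294 and 0.0275; 0.649 and 0.712 with an estimated correlation), and both calls ended without wild type 3 (0.157 and 0.0608), wild type 4 (0.203 and 0.245), F341V 2 (0.128 and 0.0582) or F341V 3 (0.0877 and 0.0854), glycolysis also without F341V 1 (0.101). Without wild type 4 alone 6 lists passed, and without F341V 1 alone 9 passed. The 22 tested components of the PI3K, AKT and mTOR pathway had a median change of -0.02 and the 22 FOXO target genes of -0.09, with no member past the test and camera adjusted p-values of 0.777 and 0.0616.

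Fibroblasts with deleted Pten differed in 1046 genes from wild type fibroblasts that also carried Cre, 726 higher and 320 lower. The surface sialomucin gene Cd34 was 7.42-fold higher, at 10.53 ± 0.12 against 7.63 ± 0.70 (SD, n = 4; adjusted p = 9.44e-06), and the secreted factor gene Angptl7 was 7.09-fold higher, at 10.28 ± 0.53 against 7.46 ± 0.73 (adjusted p = 0.000192). Fbxo32, a muscle ubiquitin ligase gene known as a FOXO target, fell from 10.03 ± 0.20 to 8.47 ± 0.14 (adjusted p = 7.46e-06), and the ligand gene Wnt4 from 9.82 ± 0.45 to 7.98 ± 0.10 (adjusted p = 7.04e-05). Cd34 and Fbxo32 in the deletion lay near wild type without Cre (10.01 to 10.18 and 8.28 to 8.69), with wild type with Cre apart. Angptl7 and Wnt4 in the deletion lay beyond both wild type groups (7.94 to 8.38 and 8.22 to 8.88 without Cre). Tmem178, Crispld2 and Jag1, named below, also lay nearer to wild type without Cre than to wild type with Cre in the deletion. Jag1 was at 9.68 to 10.06 in the deletion, 9.83 to 10.60 without Cre and 11.09 to 12.01 in wild type with Cre. Strain and vector differ between the wild type groups, so which group set such changes could not be told. Other strong rises were Msln (mesothelin, log2 change 2.14), Prg4 (lubricin, 2.05), the interferon-induced Ifit3 (1.98), the angiotensin receptor gene Agtr2 (1.90), the peroxisomal thiolase gene Acaa1b (1.82), the aminopeptidase gene Enpep (1.81), the protease inhibitor gene Serpinb1a (1.69) and the matrix gene Spon2 (1.66). Other strong falls were Tmem178 (-2.20), the cytokine signalling inhibitor Socs2 (-2.17), the gap junction gene Gjb2 (-2.14), Crispld2 (-2.04), Fndc1 (-1.88), the monoacylglycerol lipase gene Mgll (-1.74), the Notch ligand gene Jag1 (-1.63) and the chemokine gene Cxcl14 (-1.61). Adjusted p-values of these 16 genes lay between 0.000148 and 0.0484. Some of them also differed between arrays of the same genotype without Cre. Serpinb1a was at 6.83, 6.69, 8.74 and 8.72 in wild type 1 to 4 and at 7.29, 6.90, 7.04 and 9.09 in F341V 1 to 4. Acaa1b was at 5.85, 5.93, 7.32 and 7.21 and at 6.10, 6.21, 5.92 and 7.87 in turn. Socs2 was lower in wild type 3 and 4 (7.07 and 7.60) than in wild type 1 and 2 (8.20 and 8.53). Changes of this kind were thus also seen without the deletion. Non-overlapping arrays were seen for 2517 genes, or 19.8%, against the 2.86% that chance gives.

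The groups of this comparison also differed by sex. Y-linked genes averaged 8.42 or more on each array of wild type with Cre and on deletion 2, and 4.42 or less on deletion 1, 3 and 4, and Xist had a log2 change of 4.25 (SE 1.53, adjusted p = 0.105). With the Y-linked level as a covariate 482 genes were called, 461 of them among the 1046, and all 1046 kept their sign. The count was 580 without deletion 2, 631 without wild type with Cre 1 and 669 without deletion 4. Wild type 3, wild type 4 and F341V 4 add to the shared spread, and without them 2320 genes were called, among them the 1046, while array weights gave 2776. With only the groups compared in the fit 1130 genes were higher, against 726. The split into higher and lower depended on scaling, at 475 and 433 after quantile normalization and 402 and 480 after median centring. Of the named genes, Serpinb1a lost its call without any 1 of the 8 arrays (adjusted p 0.0802 to 0.11). Prg4 lost it without wild type with Cre 1 or 2 or deletion 2, 3 or 4 (0.0507 to 0.0956) and Msln without wild type with Cre 1 or 2 or deletion 2 (0.0531 to 0.0629). Agtr2 (0.0506 to 0.0717) and Enpep (0.0515 to 0.0583) lost it without wild type with Cre 1 or 4 or deletion 1 or 2. Prg4, Agtr2, Enpep, Serpinb1a and Ifit3 also lost it with the Y-linked covariate, at 0.0522, 0.0517, 0.0665, 0.12 and 0.0695, though their log2 changes there were 2.51, 2.24, 2.00, 1.86 and 1.96. With the mean of all probe sets Socs2 changed by -0.95, Fndc1 by -1.02 and Spon2 by 0.86, each still past the threshold.

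Contractile genes fell with the deletion. Of 15 tested members 8 fell, 1 rose and 6 did not pass the test, and 11 fell when adjusted over the list alone (camera adjusted p = 1.46e-11; adjusted p = 0.0175 with an estimated correlation). The leiomodin gene Lmod1 fell by 0.96 on the log2 scale (SE 0.12), the smooth muscle actin gene Actg2 by 1.12 (SE 0.16), the myosin light chain gene Myl9 by 0.58 (SE 0.08) and the transgelin gene Tagln by 0.38 (SE 0.06), with adjusted p-values of 0.000303, 0.000761, 0.000699 and 0.00126. Of 16 genes of the TGF-beta and BMP response 7 fell and 10 fell when adjusted over the list alone, with a median of -0.46 (camera adjusted p = 1.68e-08; adjusted p = 0.00106 with an estimated correlation). They included the ligand genes Tgfb3 at -1.11 (adjusted p = 5.53e-06), Tgfb2 at -0.62 (0.00939) and Tgfb1 at -0.67 (0.0157) and the matricellular gene Ccn2 at -0.79 (0.0078). Of 14 WNT response genes 4 fell and 1 rose, with a median of -0.21 (camera adjusted p = 0.000616; adjusted p = 0.0175 with an estimated correlation) and 5 fell when adjusted over the list alone. Nkd2, an inhibitor of WNT signalling, fell by 1.26, Ccn5 by 1.41 and Ccn4 by 0.91, and the antagonist gene Dkk2 rose by 0.91. Collagen and matrix genes had 5 falls among 29, including Col8a1 at -0.64, Col12a1 at -0.64, Col4a1 at -0.49 and Thbs1 at -0.50, with 10 lower when adjusted over the list alone (camera adjusted p = 6.13e-07; adjusted p = 0.498 with an estimated correlation).

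Metabolic and stress genes moved in both directions with the deletion. Of 20 genes of cholesterol synthesis and uptake 5 fell, and 11 fell when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 3.91e-09; adjusted p = 0.304 with an estimated correlation). The sterol carrier gene Stard4 fell by 0.86 (SE 0.16), Sqle by 0.40 (SE 0.09), Msmo1 by 0.38 (SE 0.09) and Lss by 0.50 (SE 0.12). None of 14 fatty acid synthesis genes changed (median 0.03, camera adjusted p = 0.765). Of 14 hypoxia response genes 4 rose and 7 rose when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.00138; adjusted p = 0.102 with an estimated correlation), among them Ankrd37 at 0.93 (SE 0.14), Higd1a at 0.37 (SE 0.07), Ero1a at 0.39 (SE 0.10) and the pyruvate dehydrogenase kinase gene Pdk1 at 0.47 (SE 0.14). The glycolytic enzyme gene Tpi1 rose by 0.33, alone among 14 glycolysis genes over all genes, and 4 rose when adjusted over the list alone (median 0.17; camera adjusted p = 0.0066; adjusted p = 0.547 with an estimated correlation). Of 20 p53 target genes 8 rose and none fell, and 10 rose when adjusted over the list alone (median 0.34; camera adjusted p = 3.37e-06; adjusted p = 0.304 with an estimated correlation). They included Mdm2 (0.48), which encodes the ligase that degrades p53, Ei24 (0.26), the death receptor gene Tnfrsf10b (0.43) and the polo-like kinase gene Plk2 (0.36). No mitosis or replication gene passed the test over all genes. The lists had medians of -0.28 and -0.16 (camera adjusted p = 0.00259 and 0.0297, both 0.942 with an estimated correlation). The mitosis list averaged 9.29, 9.76, 10.39 and 10.10 in wild type with Cre 1 to 4 and 9.49, 9.52 and 9.44 in deletion 1, 2 and 4, with deletion 3 above them, and its call ended without wild type with Cre 3 (0.205) and after median centring (0.0725). The replication call ended without wild type with Cre 3 (0.48), wild type with Cre 4 (0.172), deletion 1 (0.137) or deletion 2 (0.0616).

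Single components and targets of the pathway that Pten opposes changed in both directions, and neither list moved one way by camera. Of 22 PI3K, AKT and mTOR pathway genes 2 rose and 2 fell (median 0.05, camera adjusted p = 0.76; fry's test for change in either direction, adjusted p = 0.000111). The regulatory subunit gene Pik3r3 rose by 1.01 (SE 0.18) and Mtor by 0.32 (SE 0.06), and Rictor fell by 0.72 (SE 0.14) and Rheb by 0.24 (SE 0.06). The list's median was 0.00 after quantile normalization and -0.01 after median centring. Of 22 FOXO target genes 2 rose and 1 fell, with Fbxo32 at -1.56, Bcl6 at 0.66 (SE 0.12) and Tle1 at 0.33 (SE 0.08), and the list had a median of 0.20 (camera adjusted p = 0.765; fry's test for change in either direction, adjusted p = 0.000157). Growth factor receptor genes held 3 falls among 21, Igf1r at -0.66 (SE 0.08), Pdgfrb at -0.72 (SE 0.15) and the ligand gene Vegfc at -0.67 (SE 0.19). In the ERK feedback list Dusp4 fell by 1.39 and Spry1 by 0.96, while Etv5 rose by 0.34 and the cyclin gene Ccnd1 by 0.64 (3 rose and 2 fell of 19). The cytokine gene Il6 fell by 1.39 (SE 0.18, adjusted p = 0.000534), and the chemokine gene Ccl5 rose by 0.76. In the NRF2 list Hmox1 rose by 0.64 and Srxn1 by 0.44 (2 of 15; camera adjusted p = 0.109, and 0.0437 after quantile normalization and 0.0401 after median centring). Of 26 interferon-stimulated genes 2 rose, Ifit2 by 0.71 and Ifit3, and 23 were above 0 (median 0.37, camera adjusted p = 0.0865, and 0.0158 after quantile normalization and 0.00439 after median centring). Their list mean ran from 8.31 to 9.84 in the deletion arrays and from 7.99 to 9.32 in wild type with Cre. Among markers of other cell types, the neuronal genes Nefl (1.56), Stmn2 (0.89) and Nefm (0.69) rose (3 of 11; camera adjusted p = 0.3), the pericyte genes Mcam (-1.04) and Pdgfrb fell (2 of 9; 0.577), the endothelial gene Flt1 fell by 1.09 (1 of 6; 0.313), and no skeletal muscle gene changed (12 tested; 0.731).

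**Figure D2:**
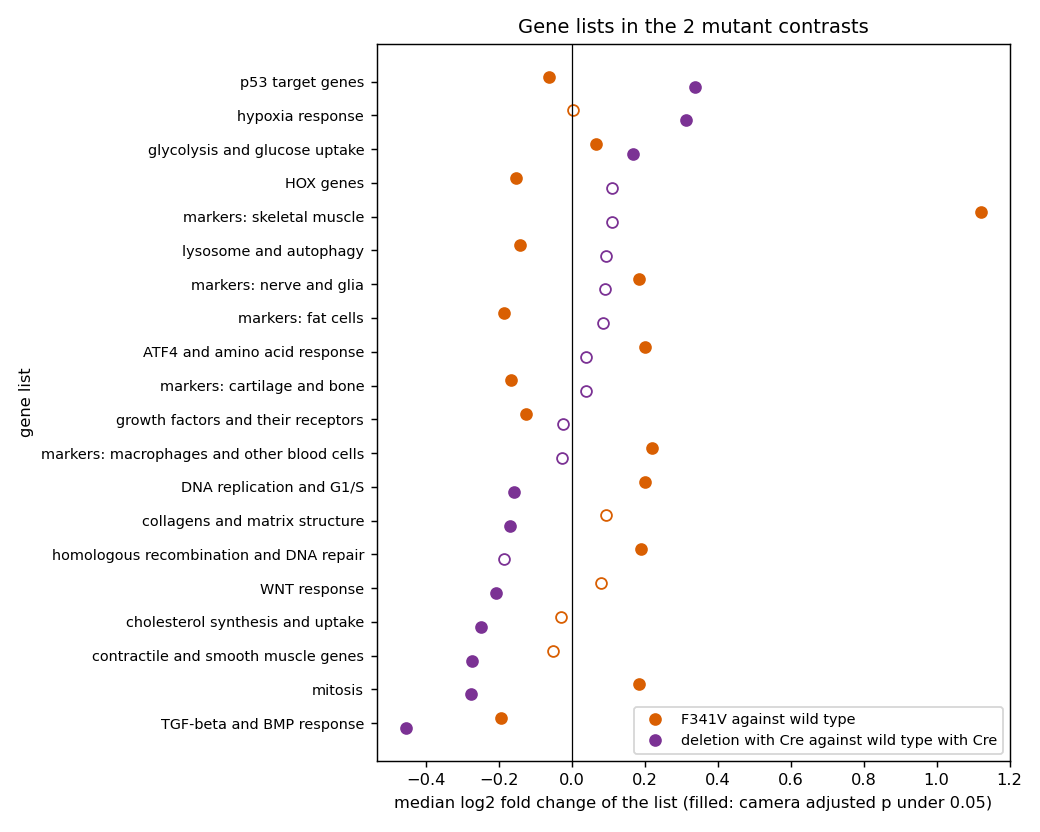
Median log2 fold change of each gene list past camera's threshold in at least 1 mutant contrast, for F341V against wild type and for the deletion with Cre against wild type with Cre, with filled points for camera adjusted p under 0.05. The TGF-beta and BMP list lies below 0 in both contrasts, and the p53 target list is at 0.34 in the deletion and -0.07 in F341V.

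The effects of the F341V alteration and of the deletion were compared gene by gene, each against the wild type of its own strain and vector. Lipo3 and Nefl were higher in both mutants, by 1.63 and 1.56 in the deletion (adjusted p = 1.37e-05 and 5.53e-06), where 0.114 shared rises are expected for independent lists (Fisher's exact p = 0.00325). Lipo3 lies next to Pten, altered in both mutants, so strain DNA there could also give a shared rise, which was not tested. Both genes lay below the filter level of log2 6.57 in wild type with Cre. Nefl was at 4.57 to 5.2 there and Lipo3 at 6.19 to 6.48, so the sizes of these rises are uncertain. Thbs1 was lower in both mutants, by a log2 change of -0.48 in F341V and -0.50 in the deletion (0.0754 expected, Fisher's exact p = 0.0735). Als2cl was lower in F341V and higher in the deletion (0.34, adjusted p = 0.0359, and 0.0171 to 0.208 over its alternatives, in 9 of which the call ended). The mutants lay at like levels, 6.62 to 6.94 in F341V and 6.70 to 6.97 in the deletion. The wild types differed, at 7.47 to 7.65 without Cre and 6.31 to 6.66 with Cre, which is around the filter level. The opposite signs of Als2cl thus rest on the wild type groups. Tgfa had a log2 change of 0.04 in the deletion (adjusted p = 0.806). Across the 12735 genes the effects had a Pearson correlation of -0.092 and a Spearman correlation of -0.0743, where genes are not independent replicates, and relabelled arrays gave correlations from -0.446 to 0.566, 77 of 99 of them as far from 0. The correlation was 0.072 without wild type 3, 0.038 without wild type 4 and 0.12 without the 3 arrays apart. The 726 genes higher in the deletion had a median of 0.02 in F341V (camera p = 0.203; p = 0.718 with an estimated correlation) and the 320 lower genes of -0.02 (camera p = 0.00601; p = 0.228 with an estimated correlation). The set of 726 higher genes passed camera without wild type 3 (0.00144), F341V 1 (0.0251) or F341V 2 (0.029), with medians of 0.045, 0.022 and 0.033. The set of 320 lower genes did not pass camera without wild type 1 (0.102), wild type 2 (0.163, with a median of 0.002) or F341V 4 (0.421).

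The difference between the mutant effects passed the test for 234 genes. Cd34 rose with the deletion and had a log2 change of -0.17 in F341V, a difference of -3.07 (SE 0.34, adjusted p = 0.000937), and Angptl7 had a difference of -3.33 (SE 0.46, 0.00576). Such differences rest on both wild type groups, which themselves differed, and Cd34 was lower in wild type with Cre than without. Tgfb3, the Rho GTPase gene Rhoj, Lurap1l, the zinc exporter gene Slc30a1, Fbxo32 and the T cell receptor segment Trav9d-3 fell in the deletion and were not called in F341V, and the test of the difference gave 1.09, 0.85, 0.90, 0.78, 1.21 and 0.94 in turn (adjusted p from 0.000937 to 0.00733). Als2cl (-1.11) fell in F341V and rose in the deletion, and Tgfa (-0.62) fell in F341V. The difference for Tgfa did not pass with the mean of all probe sets (-0.237, limma adjusted p = 0.103). Among lists, WNT response genes and TGF-beta and BMP genes differed, with medians of 0.33 and 0.28 (camera adjusted p = 0.00116 and 0.00182; both 0.049 with an estimated correlation). Contractile genes (0.24) and p53 target genes (-0.41) also differed by camera (3.19e-07 and 1.34e-07), and had adjusted p-values of 0.094 and 0.224 with an estimated correlation. Of the 234 genes 78 had a positive and 156 a negative difference, a split that was 83 and 94 after quantile normalization and 82 and 89 after median centring. The count was 666 without F341V 4, and it was 58 without F341V 2, 64 without deletion 2, 80 without F341V 1, 87 without wild type with Cre 1, 95 without wild type 3, 117 without F341V 3, 121 without deletion 4, 123 without wild type 4 and 144 without wild type with Cre 2. With the Y-linked covariate it was 114.

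**Figure D3:**
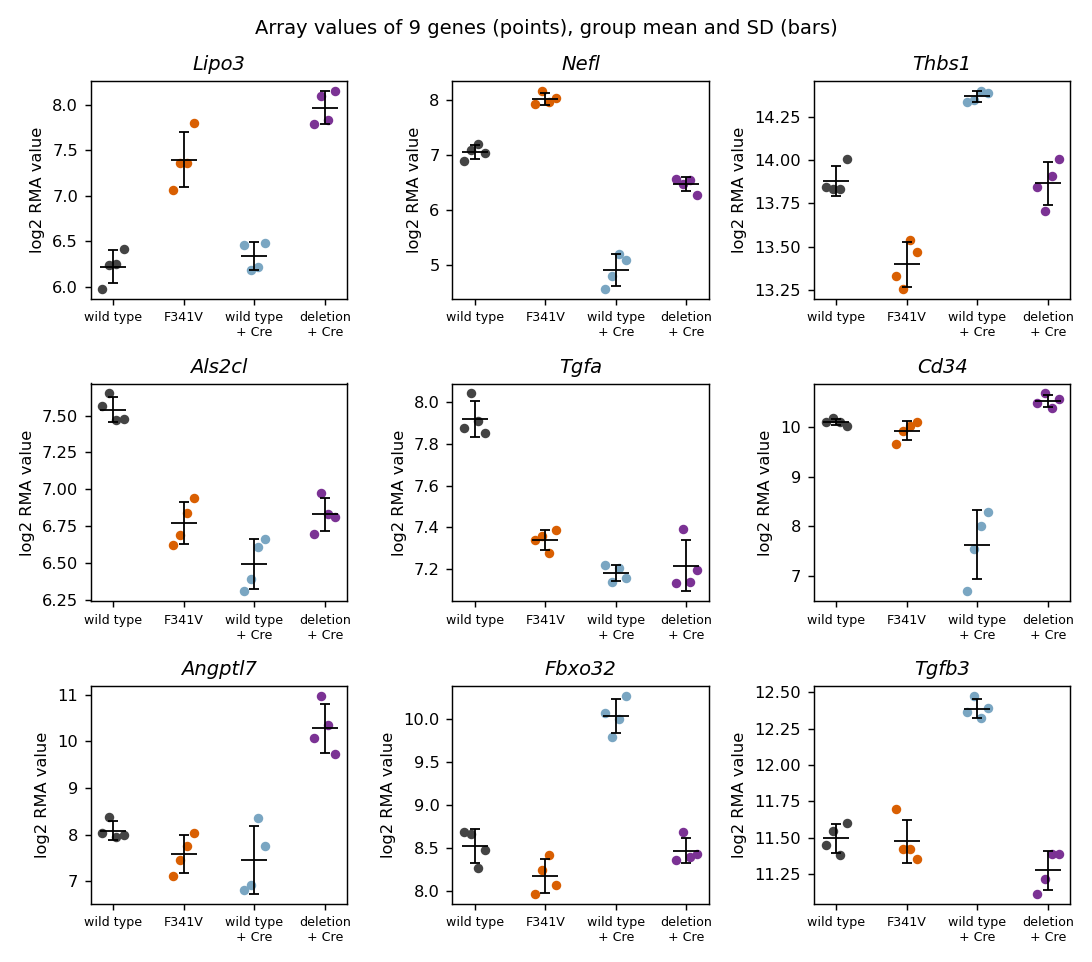
Log2 RMA values of 9 named genes on each array (points) with the group mean and SD (bars), 4 arrays in each group. Lipo3 and Nefl are higher in both mutants than in their own wild type, and Cd34 and Angptl7 are higher in the deletion than in wild type with Cre.

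The wild type groups differed from each other in 3205 genes, 1010 higher and 2195 lower with Cre. Strain and vector changed together here, so the contrast describes the distance between the control groups. Mycn, a transcription factor gene of the Myc family, was 59.4-fold higher with Cre, at 14.02 ± 0.18 against 8.13 ± 0.20 (SD, n = 4; adjusted p = 4.07e-14), and stood at 14.47 ± 0.03 in the deletion. This came from 1 of its 3 probe sets. The others, looked at after these values were seen, were at 7.26 ± 0.27 against 7.56 ± 0.30 and at 6.90 ± 0.07 against 7.10 ± 0.19 (adjusted p = 0.219 and 0.106 over all probe sets). Ccl8, Tmem178, Ppbp and Clec2d were higher by 3.13, 2.69, 2.67 and 2.61. The cartilage collagen gene Col2a1 was 20.0-fold lower with Cre, at 8.50 ± 0.48 against 12.82 ± 0.35 (adjusted p = 1.06e-06), and Enpep, Bex1, Krt7 and Cd34 changed by -2.82, -2.50, -2.47 and -2.47. Of 20 cholesterol genes 19 were lower (median -0.63; camera adjusted p = 1.07e-10; adjusted p = 0.143 with an estimated correlation) and of 14 fatty acid synthesis genes 12, among them Fasn at -0.99 and Srebf1 at -0.90 (camera adjusted p = 2.28e-08; adjusted p = 0.116 with an estimated correlation). Of 26 interferon-stimulated genes 10 were higher (median 0.75; camera adjusted p = 5.45e-08; adjusted p = 0.49 with an estimated correlation), and of 19 NF-kB targets and chemokines 9, including Cxcl5 at 2.32 and Ccl7 at 1.78 (camera adjusted p = 2.97e-06; adjusted p = 0.00489 with an estimated correlation). Of 12 markers of cartilage and bone 10 were lower (camera adjusted p = 4.54e-06; adjusted p = 0.0121 with an estimated correlation). Of 23 mitosis genes 6 were lower (median -0.75; camera adjusted p = 0.000192; adjusted p = 0.57 with an estimated correlation), with 23 lower without the 3 arrays apart (median -1.21) and 0 past the test over all genes with the Y-linked covariate (median -0.59). After quantile normalization 1452 genes were higher and 1354 lower, and with the Y-linked covariate 1232 genes were called.

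Genes next to Pten on its chromosome were counted because DNA of another strain can travel with an altered allele. Of the 200 tested genes nearest to Pten, 1 was called in F341V (0.5%, against 0.0319% elsewhere; Fisher's exact p = 0.0761) and 16 in the deletion (8%, against 8.22%; Fisher's exact p = 1). The called gene in F341V was Lipo3. With an unadjusted p under 0.01, 9 of the 200 genes stood out in F341V (4.5%, against 1.52%; Fisher's exact p = 0.00421) and 25 in the deletion (12.5%, against 12%; Fisher's exact p = 0.827). With 50 genes on each side the share of calls in F341V was 1% (Fisher's exact p = 0.0387), and with 200 on each side 0.262% (Fisher's exact p = 0.141). With 200 on each side the share with an unadjusted p under 0.01 was 2.62% (Fisher's exact p = 0.0924).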

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

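The tests of sex and of slower division for the 3 arrays apart, of genes with a single probe set, and of strain DNA carried along were chosen only after the results were seen, as were the settings that left out or adjusted for these arrays and the setting with the Y-positive deletion array. The spread of arrays within groups was screened for 176 groups of 4 arrays, and in 12 (6.82%, 3 for genes and 9 for lists) 1 array lay far from the other 3. Chance gives about 1 in 20 groups, so single cases carry little weight, but 5 of the 9 for lists fell on F341V 4. That array was at 10.13 for mitosis (mean of the others 11.13, gap over range 0.942), 10.31 for DNA replication (11.19, 0.953), 8.06 for DNA repair (8.82, 0.973), 11.23 for p53 target genes (10.8, 0.852) and 9.2 for fat cell markers (8.28, 0.848). F341V 3 was apart for cartilage and bone markers (8.25 against 7.99, 0.962), wild type with Cre 4 for HOX genes (8.11 against 8.25, 0.946), wild type with Cre 3 for cartilage and bone markers (7.32 against 7.15, 0.853) and deletion 3 for mitosis (10 against 9.48, 0.859). Among genes, wild type 4 was apart for Thbs1 (14.01 against 13.84, 0.926), wild type 2 for Mycn (7.83 against 8.23, 0.831) and F341V 2 for Slc30a1 (8.4 against 8.3, 0.935).

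The same structure set wild type 3, wild type 4 and F341V 4 apart from the other 5 arrays without Cre. The sex of the embryos was argued against as the cause, since only 5 of 8 arrays matched in Y-linked state. Quantile normalization left 55.3% of the variance of deviations on their main component, against 55.1%. RMA had already equalised the distributions of the arrays, so this test could not decide on the authors' normalization. Slower division remained open: in 3 of 3 arrays both the mitosis and the replication list lay below all 5 others, though this was noticed and tested on the same arrays and may be one side of a wider difference in culture, which the labels do not describe. Regrouping the 8 arrays showed that chance could not be excluded for the F341V count, since 6 of 35 splits gave at least its 5 genes, the highest other 3487. The 5 splits with so many genes, from 2478 to 3487, parted the 3 arrays from others, which points to this structure of the samples.

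The 1046 genes called in the deletion stood out against chance, with 1 of 35 splits as large (highest other 1), as did the 3205 genes between the wild type groups (1 of 35, highest other 6) and the 234 genes of the difference (2 of 100 splits, highest other 636). Sex was unequal in the deletion contrast, and 1 comparison argued against it as the cause for the genes as a whole. Genes called without deletion 2, with either pair of controls held out for its change (393 and 435 genes), changed in that Y-positive array by 0.985 and 1.12 times as much as in the other deletion arrays, with the same sign in 84% and 96.1%. This rests on 1 deletion array. With the Y-linked covariate all 1046 genes kept their sign, with a median size of 0.468 against 0.435, and 461 stayed past the threshold. They were called on these same arrays, so keeping the sign adds little. Of 393 X-linked genes 10.7% were called, against 8.13% of other genes (Fisher's exact p = 0.0757). An effect of sex on single genes was not excluded. With the division level as a covariate the median size of the called genes was 0.955 times its value. That level overlapped between the groups, at 9.47 to 10.43 in wild type with Cre and 9.65 to 10.09 in the deletion. The covariate could thus take away little of a group difference, and its slope also came from the 3 arrays apart. The test did not decide on slower division, and an effect on single genes was not excluded. Culture day or batch remained untested.

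Next to Pten, the 9 genes with an unadjusted p under 0.01 in F341V were Ankrd2 (0.28), Ch25h (0.85), Fas (-0.79), Il33 (0.87), Jak2 (0.41), Lipa (0.54), Lipo3, Loxl4 (-0.63) and Stx3 (-0.49), all but Lipo3 named after their values were seen. Of 8483 windows of 200 genes elsewhere 0.413% held as many, with a highest count of 9. These windows overlap, so their share does not measure chance, and an uneven spread of changed genes along the chromosomes was not excluded. Loss of Pten function was argued against for the 9 as a whole, since 2 of 9 changed alike in the deletion. However, 6 of 9 had the same sign there, and it stayed open for Lipo3, Lipa and Il33. The floxed allele also alters Pten in a mixed stock, so a like change in the deletion cannot tell loss of function from strain DNA. In 4 of 4 genes with other probe sets at least 1 of these changed alike, which argued against strain variants under the probes of 1 probe set. Lipa's other probe sets went opposite ways, at 1.63 and -0.52, so the question stayed open for Lipa. It could not be settled for 5 genes with a single probe set. Strain DNA carried along with the altered allele is a candidate explanation: 6% of the nearest 100 genes stood out, against 0.552% of 181 genes further away. It is a hypothesis found and tested on the same arrays, and no marker of strain was used here.

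The effects of the mutants differed by a test of the difference itself for 10 genes named by rule: Rhoj (0.846), Tgfb3 (1.09), Cd34 (-3.07), Lurap1l (0.896), Als2cl (-1.11), Slc30a1 (0.779), Angptl7 (-3.33), Fbxo32 (1.21), Tgfa (-0.616) and Trav9d-3 (0.941). Lists differed too, by camera, with median differences of 0.266 for cholesterol, -0.219 for hypoxia, 0.387 for replication, 0.498 for mitosis, 0.301 for DNA repair, -0.412 for p53 targets, 0.25 for collagens, 0.243 for contractile genes, 0.277 for TGF-beta and BMP, 0.326 for WNT, -0.23 for lysosome, 0.211 for ribosome biogenesis and 1.14 for skeletal muscle. With an estimated correlation only TGF-beta and BMP and WNT stayed past the threshold (both 0.049), and the others had adjusted p-values of 0.506 for cholesterol, 0.224 for hypoxia and p53 targets, 0.563 for collagens, 0.094 for contractile genes, 0.518 for skeletal muscle and 0.729 for replication, mitosis, DNA repair, lysosome and ribosome biogenesis. The lysosome and ribosome lists lost their call without some arrays, among them wild type 3 (0.144 and 0.298) and wild type 4 (0.171 and 0.318).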

How the results depend on the processing

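Settings that concern the 3 arrays apart or only Y-positive arrays were chosen after the data were seen, and the cause of a change was not tested unless its construction shows it. No named gene changed direction: 882 values under planned settings kept their side of the threshold and 52 did not, and 95 and 32 under added ones. In every setting 0 of 5 named genes of F341V, 11 of 24 of the deletion, 0 of 10 of the difference and 10 of 10 of the wild type contrast kept their call. Counts are given for F341V, the deletion, the difference and the wild type groups in turn (5, 1046, 234 and 3205). Stricter by construction were an adjusted p under 0.01 (368, 21 and 1444 for the last 3) and 1.5-fold (3, 304, 151 and 806). The mean of all probe sets moved Als2cl in F341V to -0.509, the differences of Tgfa and Trav9d-3 to -0.237 and 0.534, and Mycn between the wild type groups to 1.80, and the 1 Y-positive deletion array moved Msln, Ifit3 and Fndc1 to 3.29, 1.31 and -2.87. All probe sets gave 9, 2159, 374 and 6609, and array weights 36, 2776, 941 and 6242, with 16 lists for the deletion, 11 shared genes and a correlation of 0.094. The 3 arrays as a covariate gave 13, 2671 and 743, 6 shared genes, a correlation of 0.132 and a median of 0.042 for genes higher in the deletion (p = 0.000662), and leaving them out gave 15, 2320, 0.12 and 0.035 (p = 0.0175). Only these arrays, fewer by construction and with 1 F341V array assumed to vary like the others, gave 0 genes and 5 lists for F341V and 1 gene for the difference. The Y-linked covariate gave 482, 114 and 1232 for the last 3, and the 1 Y-positive deletion array 93 and 14. Genes above the 50th percentile alone gave 0 genes, 8 lists and 0 shared genes for F341V, where of the 5 called genes only Thbs1 was still tested. Fitting only the groups compared gave 2019 for the wild type groups and 1130 genes higher in the deletion, against 726. The replicate block gave 10 for F341V and 426 for the difference, with correlations of same-numbered deviations from -0.536 to 0.851, so numbers did not pair arrays. An estimated correlation left 2, 3 and 2 lists of 15, 10 and 13, fry 2 and 6 for F341V and the difference, and the genes lower in the deletion were then no longer past (-0.019, p = 0.228 and 0.284). By Fisher's exact test next to Pten, 50 genes on each side gave 1% (p = 0.0387) and 10% (p = 0.465), and an unadjusted p under 0.01 gave 4.5% (p = 0.00421) and 12.5% (p = 0.827). Leaving out each array in turn gave 4 to 26, 580 to 840, 58 to 666 and 2277 to 3537 genes, 6 to 16, 9 to 13 and 11 to 18 lists, 2 to 4 shared genes, and correlations from -0.211 to 0.072, reversed without wild type 3 and wild type 4 (0.038). The sets higher and lower in the deletion ranged from -0.014 to 0.045 and from -0.044 to 0.002, reversed without wild type 2, the first past camera without wild type 3 (0.00144), F341V 1 (0.0251) or F341V 2 (0.029), and those of F341V from 1.552 to 1.649 and from -0.024 to 0.062. Scaling moved the median of all genes by at most 0.068. Values near the lowest levels limit small changes, as array signal there is close to background.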

Other observations

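The settings described first here were chosen after the data were seen. With the 3 arrays apart as a covariate, 8 genes joined the 5 called in F341V, all named after their values were seen. Lipa, the lysosomal acid lipase gene next to Pten, was higher by 0.69 on the log2 scale, the neuropeptide precursor gene Scg2 by 1.06, the glial gene Fabp7 by 1.22 and the muscle gene Srl by 0.70. The Lipa value comes from 1 probe set. Its others went opposite ways in the main fit, at 1.63 and -0.52, so a rise of the gene is uncertain. The death receptor gene Fas, also next to Pten, changed by -0.57, Llgl2 by -0.49, Tgif1 by -0.29 and the ion channel gene Trpv4 by -0.62. With these arrays left out instead, Srl (limma adjusted p = 0.103), Tgif1 (0.192) and Trpv4 (0.173) did not pass. Lipa, Scg2, Fabp7, Fas and Llgl2 passed there (0.0256 to 0.0446).

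Genes that set out position along the body differed between the wild type groups. Of 37 regional transcription factors of embryonic mesenchyme 14 were lower and 6 higher with Cre and the mixed strain, and Foxd1, Foxc1, Pitx1 and Tbx3 changed by -2.19, -1.23, -0.80 and -0.37 (limma adjusted p from 1.53e-05 to 0.000421). Of 25 HOX genes 9 were lower and 1 higher, with Hoxa5 at -2.06, Hoxb6 at -1.04 and Hoxa7 at -0.96. The HOX list averaged 8.26, 8.25, 8.61 and 8.65 in wild type 1 to 4 and 8.24, 8.25, 8.25 and 8.11 in wild type with Cre 1 to 4. Its lower mean with Cre thus rested mostly on wild type 3 and 4, which are among the arrays apart. Over all genes 3205 of 12735 were called in this contrast. Of 15 imprinted genes 7 were lower, with Cdkn1c at -1.43 and Igf2 at -0.50. None of these lists passed camera (adjusted p = 0.265, 0.265 and 0.0595). Imprinted genes did after quantile normalization (0.0204) and median centring (0.0216) and with the Y-linked covariate (0.0463). Fry's test for change in either direction passed in each (adjusted p = 2.27e-14, 5.84e-05 and 5.61e-08). It passed for 29 of 36 lists in this contrast, so it does not single out these lists. Epithelial markers held 4 falls and 1 rise among 11, including Krt19 at -2.18 and Krt18 at -2.21 (camera adjusted p = 0.253). Cdk inhibitors and secreted factors of senescent cells held 8 rises and 1 fall among 21, with Mmp3 at 2.13 and Il6 at 1.32 (camera adjusted p = 6.52e-06; adjusted p = 0.0121 with an estimated correlation).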
